A study of Mus musculus with 9 samples.

How the data were processed

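Bulk RNA sequencing was done on mouse left ventricle in 9 libraries. The tissue is described as infarct core and the region around it, which sham hearts do not have. The groups are sham surgery, myocardial infarction (MI) and MI with BPD treatment (MI+BPD), with 3 libraries each. The labels place the tissue at day 14 after MI and give no time of their own for sham; they do not spell out BPD, its dose or its schedule beyond a treatment aimed at the proliferative phase. RNA was extracted with TRIzol, samples with an RNA integrity number above 7.0 went on to VAHTS Universal V6 libraries, and sequencing was 150 bp paired-end on DNBSEQ-T7.

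The deposited values are raw read counts per gene symbol, whole numbers with a different total in each library and no normalization by the authors. The labels name STAR for alignment, without a version, and 3 genome builds (mm10, GRCm39 and mm39) without saying which one was used for what. The counting program, its strand setting and the annotation are not given in the sources used here. Because the build is unclear, genes are identified by symbol and no coordinates are printed. The table holds 55367 symbols with no duplicates, of which 26591 have no count in any library; 96.3% of the symbols are gene names of GENCODE M21. All 9 columns were used. Total counts ran from 14451410 to 19269072 per library. Reads were counted without molecular identifiers, so counting intervals and floors cover counting error only. A single read is worth 0.0692 CPM (read count scaled by library size) in the library with the fewest counts.

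Counts were analysed in R 4.3.3 with edgeR 4.0.16: trimmed mean of M values (TMM) factors, the filterByExpr filter (minimum count 10, minimum total 15) and a robust quasi-likelihood fit of all 9 libraries by group, with 6 residual degrees of freedom. The 15138 genes tested hold 99.9% of all counts, and the biological coefficient of variation was 0.167. Tests were 2-sided, p was adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes carry the standard error (SE) that follows from the F statistic. CPM values are TMM-scaled means with the standard deviation (SD) of 3 libraries. Where sham had 0 counts over its 3 libraries, the fold is a lower bound against 3 counts over the group; where sham had 1 to 3 counts, the ratio is given with its 95% exact binomial counting interval.

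A total of 42 gene lists (pathways, matrix classes and cell type markers) was written from textbook knowledge. They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Fry tests a list on its own without setting it against other genes, and was used in its directional form unless said otherwise. The p was adjusted over lists with at least 3 tested members, which left 41; a list of lung epithelium markers had too few. Members called are counted over all genes and, beside that, adjusted over the list alone. A list score is the mean log2 CPM (prior count 2) of the list's members in a library, compared by a 2-sided exact permutation test; with 3 libraries against 3 its smallest p is 0.1, so it cannot reach 0.05. Lists describe genes in bulk tissue and type no cells.

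The 3 comparisons were MI against sham, MI+BPD against MI, and MI+BPD against sham. Genes called in MI against sham and called with the opposite sign in MI+BPD against MI were counted as moved back. They were set beside 20 simulations of all 9 libraries in which no group differed. In these both comparisons shared the simulated MI libraries. Genes are named by a rule: the 10 higher and 10 lower called genes with the largest fold change, a mean of at least 5 CPM in the higher group, no overlap between the libraries of the groups, and a symbol that is not a predicted or clone name. Where no gene is called, the 5 of smallest p in each direction that meet the other criteria are given as not passing. To these come up to 4 members of smallest adjusted p per list described, and a panel of 17 genes for iron handling, fibroblast activation and cardiac stress. Groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

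Alternatives were DESeq2 1.42.0 and limma-voom with quality weights, other scaling factors (median-ratio, upper-quartile), no filter or a stricter filter, only the groups compared, a replicate block, other thresholds, mitochondrial and haemoglobin genes left out, and each library left out in turn. Added after the data were seen were library totals as the only scaling, MI 1 and MI+BPD 1 left out together, the cardiomyocyte list score as a covariate, and the further scaling, filter and sample choices for the gene lists. The covariate fit used the MI and MI+BPD libraries alone, and its lists were tested at the preset correlation only. The procedure was tested on simulated data with known changes: genes given a 2-fold change were called in 77.6% of cases in MI against sham, 77.6% in MI+BPD against MI and 74.6% in MI+BPD against sham, and the shares of false calls were 4.11%, 6.62% and 7.14%. These simulations drew genes independently, with a single dispersion per gene for all groups, and changed only genes above a count minimum. The real MI and MI+BPD libraries differ more among themselves than those of sham. The called shares may therefore be too high, above all for MI+BPD against MI. No duplicated libraries were found. The labels do not say whether replicates are separate animals; if they are not, the p-values measure only the spread between these samples.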

Results

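RNA of the mouse left ventricle was sequenced in 3 sham, 3 MI and 3 MI+BPD libraries. The tissue is described as infarct core and surrounding region together. Sham hearts have no infarct, so comparisons with sham may also set different parts of the ventricle side by side. Total counts were 14451410, 15337507 and 17703461 in sham, 19211255, 19269072 and 19101748 in MI, and 17006222, 17424302 and 17415507 in MI+BPD. Genes encoded by mitochondrial DNA took 34.8% ± 0.405 of the counts in sham, 13.8% ± 3.78 in MI and 20.3% ± 4.65 in MI+BPD (SD, n = 3 each). The cardiomyocyte list score was 11.02 ± 0.025 in sham, 9.48 ± 0.42 in MI and 9.998 ± 0.25 in MI+BPD (SD, n = 3 each). Heart muscle transcripts thus differ between sham and both other groups. Every comparison with sham below carries this difference, whether or not the gene group described differs. The scores of MI and MI+BPD overlap. All 9 libraries had Ddx3y counts between 1563 and 2926 and at most 40 counts of Xist.

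The comparison of MI with sham asks how the left ventricle at day 14 after infarction differs from uninjured heart. Genes of the extracellular matrix and of activated fibroblasts rose, and genes of heart muscle and its energy metabolism fell. Postn, a matricellular protein of activated fibroblasts, went from 38.0 ± 4.40 CPM in sham to 2267 ± 126 CPM in MI (SD, n = 3), a log2 change of 5.90 ± 0.29 (SE). Col1a1 and Col3a1, the main fibrillar collagens, rose by 5.43 ± 0.33 and 5.17 ± 0.26, Fn1 (fibronectin) by 5.79 ± 0.37 and Timp1, an inhibitor of matrix proteases, by 5.77 ± 0.36. Myh6, the adult myosin heavy chain of mouse ventricle, fell by 2.23 ± 0.34 on the log2 scale, while the fetal isoform Myh7 rose by 4.58 ± 0.57 and Nppa, the atrial natriuretic peptide, by 5.67 ± 0.71. In edgeR 10429 genes were called, 5594 higher and 4835 lower, and 5158 of them changed at least 2-fold, 3169 higher and 1989 lower.

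Among the called genes with the largest increase, several belong to cartilage-like and fibrous matrix. Col11a1, a minor fibrillar collagen, rose by 9.86 ± 0.66. Cilp2 (cartilage intermediate layer protein) and Cemip (a hyaluronan-degrading protein) had 1 sham count each, and their ratios were 799 (143 to 31570) and 1540 (276 to 60850). Sprr1a, a stress-induced protein, was at least 394-fold higher, Igfbp2 at least 120-fold and Tnmd (tenomodulin) at least 61.0-fold, each with 0 sham counts. Immunoglobulin genes Igkv8-30 and Igkv6-15 were at least 305-fold and 129-fold higher (24.4 ± 40.2 and 10.3 ± 15.6 CPM in MI, SD, n = 3), and Igha (3 sham counts) had a ratio of 889 (304 to 4311). Near-identical immunoglobulin family members make their counts uncertain. The B-cell chemokine Cxcl13 had 1 sham count and a ratio of 1160 (208 to 45830). Without MI replicate 1 the bounds of Igkv8-30 and Igkv6-15 were 15.1-fold and 16.6-fold and the ratios of Igha and Cxcl13 257 and 36.8. In that setting the adjusted p of Igkv8-30 was 0.0910 and that of Cxcl13 0.0604, and these 2 calls ended in 7 and 5 of the 9 fits that left out 1 library. Igkv6-15 lost its call without each sham and each MI+BPD library (largest adjusted p 0.0882), and Igha without sham replicate 1 (0.0503) or 3 (0.0702). With no filter on low counts Igkv8-30 (adjusted p = 0.196), Igkv6-15 (0.154), Cxcl13 (0.0967) and Igha (0.0739) did not pass. In limma-voom Igkv8-30 (0.0658), Cxcl13 (0.103) and Igha (0.107) did not, nor did Cxcl13 in DESeq2 or Igkv8-30 with library totals only (0.0520). Without sham replicate 3, which held the sham counts of Cilp2, Cemip, Igha and Cxcl13, these were at least 168-fold, 324-fold, 560-fold and 244-fold higher, and bounds of genes with 0 sham counts were 0.6303 times those given.

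The 10 called genes with the largest decrease include ion channels and metabolic enzymes of heart muscle. Kcnv2, a potassium channel subunit, fell by 4.72 ± 0.66 on the log2 scale, from 19.98 ± 4.90 to 0.766 ± 0.490 CPM (SD, n = 3). The sodium channel subunit Scn4b fell by 4.05 ± 0.73, the chloride channel Clcn1 by 3.85 ± 0.64, the cyclic nucleotide-gated channel subunit Cngb3 by 4.54 ± 0.66 and the water channel Aqp4 by 4.20 ± 0.58. Strit1, a micropeptide that acts on the calcium pump SERCA, fell by 4.37 ± 0.62. Changes of the carboxylesterase Ces1d, the muscle fructose bisphosphatase Fbp2, the ephrin Efnb3 and the acyl-CoA synthetase Acsm5 lay between -4.03 and -3.95.

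Fibroblast and matrix lists rose. All 34 tested matricellular and crosslinking genes rose (34 adjusted over the list alone), among them Vcan (2.93 ± 0.12), Lum (3.31 ± 0.15) and the crosslinking enzyme Loxl2 (3.42 ± 0.19). The camera adjusted p was 6.1e-34, and adjusted p = 0.34 with an estimated correlation. Of 34 fibrillar collagen and assembly genes 31 rose, 0 fell and 3 did not pass (31 adjusted over the list alone), with Col5a1 at 3.91 ± 0.16 and Col14a1 at 4.95 ± 0.22. The camera adjusted p was 6.1e-34, and adjusted p = 0.34 with an estimated correlation. In the myofibroblast list 21 of 25 rose and 2 fell, the same counts adjusted over the list alone (adjusted p = 4.1e-12, and adjusted p = 0.34 with an estimated correlation). Cthrc1, a marker of activated cardiac fibroblasts, rose by 9.08 ± 0.42 and the stretch-gated channel Piezo2 by 5.94 ± 0.35. Acta2 (smooth muscle actin) stood at 169 ± 59.6 CPM in sham and 271 ± 92.5 CPM in MI, which did not pass (adjusted p = 0.0702, 0.0234 without MI replicate 3, 0.0369 without sham replicate 3, 9.96e-03 in limma-voom and 2.7e-03 with library totals only). Of 17 matrifibrocyte genes, a cartilage-like late scar set, 15 rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 2.0e-08, and adjusted p = 0.34 with an estimated correlation), led by Comp at 9.22 ± 0.78. The list median was 5.46, or 4.48 with members near 0 counts in sham set at their bound. Matrix proteases and inhibitors rose in 20 of 24 members and fell in 1 (adjusted p = 2.7e-10, and adjusted p = 0.34 with an estimated correlation), and Ctsk and Mmp2 rose by 4.22 ± 0.18 and 3.88 ± 0.21. TGF-beta signalling rose in 24 of 31 and fell in 2 (adjusted p = 2.2e-09, and adjusted p = 0.34 with an estimated correlation), with Tgfb3 at 3.97 ± 0.27 and Tgfb1 at 1.07 ± 0.13. Basement membrane genes rose in 15 of 18 and fell in 1 (adjusted p = 1.3e-05), and genes of resting fibroblasts rose in 15 of 21 and fell in 3 (adjusted p = 2.2e-06), each with adjusted p = 0.34 with an estimated correlation. For these last 4 lists the counts adjusted over the list alone were the same.

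Heart muscle and energy genes fell together. All 42 oxidative phosphorylation genes and all 21 genes of the tricarboxylic acid cycle fell, over all genes and adjusted over the list alone, with Uqcrb at -1.87 ± 0.23 and Suclg1 at -1.98 ± 0.24. Their camera adjusted p was 2.0e-17 and 2.5e-10, and adjusted p = 0.356 with an estimated correlation for both. Fatty acid oxidation fell in 30 of 31 (30 adjusted over the list alone, adjusted p = 2.0e-13, and adjusted p = 0.34 with an estimated correlation), with the uncoupling protein Ucp3 at -3.51 ± 0.38 and the regulator Ppara at -2.35 ± 0.28. The cardiomyocyte list fell in 31 of 32 (31 adjusted over the list alone, adjusted p = 4.9e-11, and adjusted p = 0.356 with an estimated correlation), and troponin T (Tnnt2) fell by 1.69 ± 0.24. Mitochondrially encoded genes fell in 12 of 13 (13 adjusted over the list alone, adjusted p = 4.5e-06), glycolysis in 14 of 19 with 4 rising (14 and 4 adjusted over the list alone, adjusted p = 9.4e-04), and iron-sulfur cluster and heme synthesis in 23 of 27 with 0 rising (23 adjusted over the list alone, adjusted p = 7.4e-08). With an estimated correlation these 3 had adjusted p = 0.356, 0.457 and 0.34. With library totals only the glycolysis mean went from -0.83 to -0.11 (5.6e-04) and the iron-sulfur and heme mean from -0.94 to -0.22 (4.1e-08). In that last list Isca2, an iron-sulfur assembly factor, fell by 1.22 ± 0.13 and Alad, an enzyme of heme synthesis, by 1.65 ± 0.18. With an estimated correlation 0 of the 41 lists passed in this comparison (smallest adjusted p = 0.34). With fry 31 passed.

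The ferritin genes changed in opposite directions. Fth1, the ferritin heavy chain, fell from 1292 ± 70.6 to 614 ± 29.5 CPM (log2 change -1.07 ± 0.15), and Ftl1, the light chain, rose from 124 ± 9.88 to 341 ± 71.6 CPM (1.46 ± 0.17, SD, n = 3). With library totals only Fth1 was at -0.34 (adjusted p = 0.0246) and Ftl1 at 2.21 (1.5e-05). The transferrin receptor Tfrc fell by 1.59 ± 0.35 and heme oxygenase Hmox1 rose by 1.60 ± 0.36. Ferroportin (Slc40a1) was 24.3 ± 3.08 CPM in sham and 19.1 ± 5.04 in MI, which did not pass (adjusted p = 0.146, 0.0172 without MI replicate 2). Over the 35 tested members of the ferritin and iron handling list, 10 rose, 10 fell and 15 did not pass (10 and 10 adjusted over the list alone, adjusted p = 0.749, and adjusted p = 0.914 with an estimated correlation). The list mean was 0.40, its median -0.06 and its camera direction lower, so these differ in sign. The metalloreductase Steap2 (3.26 ± 0.26) and the macrophage metal transporter Slc11a1 (1.84 ± 0.20) rose. Hmox2 fell by 0.69 ± 0.08, and was at 0.04 with library totals as the only scaling. Of 31 ferroptosis and antioxidant genes 7 rose and 15 fell (7 and 15 adjusted over the list alone, adjusted p = 0.0198, and adjusted p = 0.356 with an estimated correlation), with Nqo1 at -1.11 ± 0.09 and Sod1 at -0.92 ± 0.09. The list mean was 0.56 and its adjusted p 0.0567 with library totals only, where Sod1 was at -0.19 and did not pass (0.0526), and Nqo1 was at -0.39 (3.9e-03). The list mean of -0.17 was -0.10 without sham replicate 1 and -0.09 without sham replicate 3, and both passed.

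Several immune lists and the cell cycle list were higher in MI. Macrophage and monocyte genes rose in 26 of 31 and fell in 0 (26 adjusted over the list alone, adjusted p = 3.6e-07, and adjusted p = 0.377 with an estimated correlation), among them Ccr2 (2.79 ± 0.17) and Trem2 (3.39 ± 0.23). Interferon response genes rose in 27 of 32 and fell in 1 (28 and 1 adjusted over the list alone, adjusted p = 1.6e-05, and adjusted p = 0.4655 with an estimated correlation), with Oasl2 at 1.83 ± 0.19. Cell cycle genes rose in 34 of 38 and fell in 2 (34 and 2 adjusted over the list alone, adjusted p = 2.1e-10, and adjusted p = 0.34 with an estimated correlation), with Top2a at 3.04 ± 0.13 and Mki67 at 2.62 ± 0.14. Antigen presentation rose in 14 of 15 (14 adjusted over the list alone, adjusted p = 6.1e-04), dendritic cell genes in 8 of 11 with 1 lower (8 and 1, adjusted p = 6.2e-03, or 0.0567 with library totals only), and DNA damage and senescence genes in 14 of 18 with 3 lower (14 and 3, adjusted p = 1.2e-03). With an estimated correlation these 3 had adjusted p = 0.488, 0.34 and 0.34, and with the stricter filter dendritic cell genes had 0.05265. Fetal and stress genes of the heart rose in 12 of 16 and fell in 2 (12 and 2, adjusted p = 0.0179, 0.103 without MI replicate 3 and 0.142 with library totals only), and Nppb rose by 1.63 ± 0.32. That list had adjusted p = 0.488 with an estimated correlation. Inflammatory cytokines rose in 14 of 30 and fell in 2 (12 and 1 adjusted over the list alone, adjusted p = 0.0399, and adjusted p = 0.488 with an estimated correlation). The call ended without sham 1 (0.0789), MI 1 (0.0632) or MI 2 (0.0527), without MI 1 and MI+BPD 1 (0.0599), with upper-quartile factors (0.0563), with the stricter filter (0.190) and with library totals only (0.704).

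Among other cell types, endothelial genes fell in 14 of 24 and rose in 3 (14 and 3 adjusted over the list alone, adjusted p = 0.0269, and adjusted p = 0.541 with an estimated correlation), with Flt1 at -1.19 ± 0.15. Without MI replicate 1 the adjusted p was 0.0531, without MI 1 and MI+BPD 1 0.0553, with the stricter filter 0.05265, and with library totals only the list mean was 0.37 and the adjusted p 0.113. Adipocyte genes fell in 5 of 6 and rose in 1 (5 and 1 adjusted over the list alone, adjusted p = 0.0136, and adjusted p = 0.34 with an estimated correlation). The adipocyte mean of -0.42 was -0.77, -0.28 and 0.03 without MI 1, MI 2 and sham 2, where the list passed, 0.32 with library totals only, and 3.67 with no filter on low counts, where it did not pass (0.101). Lists that did not pass were B and plasma cell (11 of 11 members rose, adjusted p = 0.142), T and NK cell (14 of 18 rose, 15 adjusted over the list alone, 2 fell, 0.0657), epicardial and mesothelial (6 of 14 rose, 4 adjusted over the list alone, 0.0802), immediate early (8 of 21 rose, 6 adjusted over the list alone, 0.0783) and hypoxia targets (8 rose and 13 fell of 26, 0.0816). The T and NK cell list passed without MI replicate 3 (0.0411) or sham replicate 2 (0.0352), as did the epicardial list without MI replicate 3 (0.0302) and the immediate early list without sham replicate 2 (7.1e-03). With no filter on low counts the T and NK cell (6.6e-03), epicardial (0.0156), immediate early (6.1e-03) and hypoxia lists (0.0364) passed, and T and NK cell also with median-ratio factors (0.0486) or a replicate block (0.0396). Also not passing were neutrophil (2 of 10 rose, 0.536), lymphatic endothelial (2 rose and 1 fell of 6, 0.703), unfolded protein response (12 rose and 4 fell of 22, 0.264), erythroid (0 of 6, 0.453), atrial (5 rose and 4 fell of 10, 0.710) and pericyte and smooth muscle (6 rose and 5 fell of 17, 0.885). Schwann cell (4 rose and 5 fell of 10, 0.980), skeletal muscle (2 and 2 of 5, 0.887) and mast cell genes (1 and 1 of 7, 0.875) did not pass either. Mean and median differed in sign for the pericyte (0.06 and -0.15), Schwann cell (0.04 and -0.25) and skeletal muscle lists (0.17 and -0.04). The mast cell list had a mean of 0.36 and a median of 0.47, but a camera direction of lower.

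The groups' libraries did not overlap in 74.4% of tested genes, where chance gives 10%. With library totals as the only scaling the median of all genes moved from 0.07 to 0.81 and 85.6% of the called genes were higher, against 53.6% with TMM, so the split into higher and lower depends on the scaling.

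The comparison of MI+BPD with MI addresses the question the series states, whether BPD treatment goes with lower fibroblast activation at day 14. No single gene was called in edgeR (0 of 15138, smallest adjusted p = 0.369). Activation markers of fibroblasts did not pass either, with changes in both directions: Postn stood at 2267 ± 126 CPM in MI and 2992 ± 919 in MI+BPD (log2 change 0.40 ± 0.24), Col1a1 at 2511 ± 776 and 2563 ± 604 (0.03 ± 0.27), and Acta2 at 271 ± 92.5 and 226 ± 33.5 (-0.27 ± 0.30, SD and SE, n = 3). The other panel genes, given below, also lay in both directions. At the level of lists, interferon response genes were lower in MI+BPD, and genes of heart muscle, energy metabolism and lymphatic endothelium were higher. These list calls rest on the preset correlation: 21 of 41 lists passed with it, 9 higher and 12 lower, and 0 passed with an estimated correlation or with directional fry. Other splits of the same libraries gave up to 28 lists at the preset correlation. With the real split, 6 of 10 gave at least 21, so the number of lists called does not set the treated group apart. With library totals as the only scaling the median of all genes moved from 0.003 to -0.203, so list means lie lower with that scaling.

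At an unadjusted p under 0.05 there were 2043 genes, 1305 higher and 738 lower, where 757 would come by chance. The number was 1202 with only the groups compared and 561 with the cardiomyocyte score as a covariate. It was 974, 832 and 822 without MI 1, MI 2 or MI+BPD 1, and 652 without MI 1 and MI+BPD 1. Without MI 3 it was 4167, and without any other single library 1620 to 2124. The excess over chance thus depends on which libraries are in the fit. DESeq2 called 51 (21 higher, 30 lower) and limma-voom with quality weights 992 (771 higher, 221 lower). Without MI replicate 3 edgeR called 1353 genes, 1126 higher and 227 lower, and without any other single library it called 0. The groups' libraries did not overlap in 13.95% of tested genes and in the scores of 8 of 41 lists, where chance gives 10% and 4.1 lists.

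The genes of smallest p, none of which passed (adjusted p = 0.369 for each), include fibroblast, antioxidant and interferon genes. On the higher side were the dermatopontin gene Dpt, a matrix protein of fibroblasts, at 294 ± 40.8 CPM in MI and 494 ± 33.1 in MI+BPD (log2 change 0.75 ± 0.12), Dpep1 (0.67 ± 0.11), Tmem267 (1.11 ± 0.15), the prostaglandin D synthase Ptgds (1.08 ± 0.21) and the quinone reductase Nqo1 (0.45 ± 0.09). On the lower side were Irf7, a transcription factor of the interferon response, at 31.3 ± 5.94 and 15.04 ± 3.72 CPM (-1.06 ± 0.19), Ifi44 (-0.95 ± 0.17), Usp18 (-0.79 ± 0.15), the basement membrane gene Nid2 (-0.66 ± 0.11) and the centrosomal gene Sfi1 (-0.77 ± 0.14). Irf7, Ifi44, Usp18, Nid2, Sfi1, Dpt, Dpep1, Tmem267, Ptgds and Nqo1 are all among the 51 DESeq2 calls.

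All 32 interferon response genes had a fold change below 0, with a mean of -0.61. Of these 0 passed over all genes and 17 fell adjusted over the list alone. Camera gave an adjusted p of 9.7e-26, and adjusted p = 0.43 with an estimated correlation. The list score was 4.61 ± 0.18 in MI and 3.99 ± 0.30 in MI+BPD without overlap (exact permutation p = 0.1, the smallest possible, SD, n = 3), against 3.51 ± 0.033 in sham. Antigen presentation, with all 15 members below 0 and a mean of -0.36, had an adjusted p of 1.9e-05, and adjusted p = 0.525 with an estimated correlation. With the cardiomyocyte score as a covariate its mean was 0.07 (0.463). Without MI+BPD replicate 1 the antigen presentation mean was -0.20 and without MI replicate 1 -0.24, and both passed, while without both it was -0.07 (0.419). The interferon mean without both was -0.39 (6.9e-19). Scaled by library totals only, the means were -0.82 for interferon (9.9e-19), -0.56 for antigen presentation (1.8e-03) and -0.54 for cell cycle genes (1.7e-06). Cell cycle genes were below 0 in 35 of 38 members (mean -0.33, adjusted p = 1.0e-08, and adjusted p = 0.474 with an estimated correlation), and adjusted over the list alone 2 fell, Ube2c (-1.17 ± 0.22) and Ccnb1 (-1.14 ± 0.26). The cell cycle score was 2.83 ± 0.18 in MI and 2.51 ± 0.081 in MI+BPD without overlap (exact permutation p = 0.1, SD, n = 3).

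Heart muscle and energy lists were higher. All 32 cardiomyocyte genes had a fold change above 0 (mean 0.49, adjusted p = 6.9e-13), including Tcap (0.84 ± 0.24) and Atp2a2, the calcium pump SERCA2 (0.89 ± 0.35), and Myh6 was at 0.77 ± 0.33 (adjusted p = 0.369). The same held for all 42 oxidative phosphorylation genes (mean 0.59, 9.1e-22), 30 of 31 fatty acid oxidation genes (0.70, 3.1e-17), all 21 genes of the tricarboxylic acid cycle (0.58, 2.3e-12), all 13 mitochondrially encoded genes (1.07, 7.2e-10), 24 of 27 genes of iron-sulfur cluster and heme synthesis (0.23, 5.4e-05) and 14 of 19 glycolysis genes (0.25, 8.3e-03, and 0.177 without MI replicate 1). In these 7 lists 0 members passed, also adjusted over the list alone. The first 5 had adjusted p = 0.474 with an estimated correlation, iron-sulfur and heme synthesis 0.494 and glycolysis 0.646. Without MI+BPD replicate 1 the means of the cardiomyocyte (0.31), oxidative phosphorylation (0.35), fatty acid oxidation (0.42), tricarboxylic acid cycle (0.34), mitochondrially encoded (0.53), iron-sulfur (0.13) and glycolysis lists (0.13) were smaller by over 1.5 times, and all passed. Without MI replicate 3 the cardiomyocyte (0.78), oxidative phosphorylation (0.90), tricarboxylic acid cycle (0.87) and iron-sulfur means (0.35) were larger by over 1.5 times. With library totals only the means were 0.29 (cardiomyocyte), 0.39 (oxidative phosphorylation), 0.49 (fatty acid oxidation), 0.38 (tricarboxylic acid cycle), 0.86 (mitochondrially encoded), 0.03 (iron-sulfur) and 0.05 (glycolysis), and all passed. Without MI 1 and MI+BPD 1 the iron-sulfur (0.06, 0.0755) and glycolysis calls (0.06, 0.494) ended. The mitochondrially encoded median was 0.81, below the mean, and mt-Co3 (3.74 ± 1.35) stood at 1358 CPM in MI+BPD replicate 1 against 51.9 and 50.5 in the other 2. Cardiomyocyte scores were 9.18, 9.30 and 9.96 in the MI libraries and 10.29, 9.88 and 9.83 in MI+BPD, so the groups overlap. With that score as a covariate fatty acid oxidation still passed (mean 0.13, 0.0200). Oxidative phosphorylation (0.01, 0.766), tricarboxylic acid cycle (0.02, 0.839), mitochondrially encoded (0.11, 0.120), iron-sulfur (-0.01, 0.726) and glycolysis genes (-0.03, 0.544) did not.

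Lymphatic endothelial genes were above 0 in 5 of 6 members (mean 0.70, adjusted p = 2.0e-05, and adjusted p = 0.43 with an estimated correlation), and 4 rose adjusted over the list alone. Mmrn1, a marker of lymphatic vessels, stood at 14.8 ± 8.72 CPM in MI and 43.1 ± 5.51 in MI+BPD (1.55 ± 0.33), Reln at 0.93 ± 0.22, the receptor Flt4 at 0.44 ± 0.14 and the transcription factor Prox1 at 0.66 ± 0.24 on the log2 scale. The list score was 4.42 ± 0.24 in MI and 5.18 ± 0.21 in MI+BPD without overlap (exact permutation p = 0.1, the smallest possible, SD, n = 3). The general endothelial list had a mean of 0.11 (adjusted p = 0.147), and passed without MI replicate 3 (0.0378) or MI+BPD replicate 3 (0.0495), and with no filter on low counts (0.0219). Its mean was -0.09 with library totals only and -0.04 with the cardiomyocyte covariate, and neither passed.

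**Figure D1:**
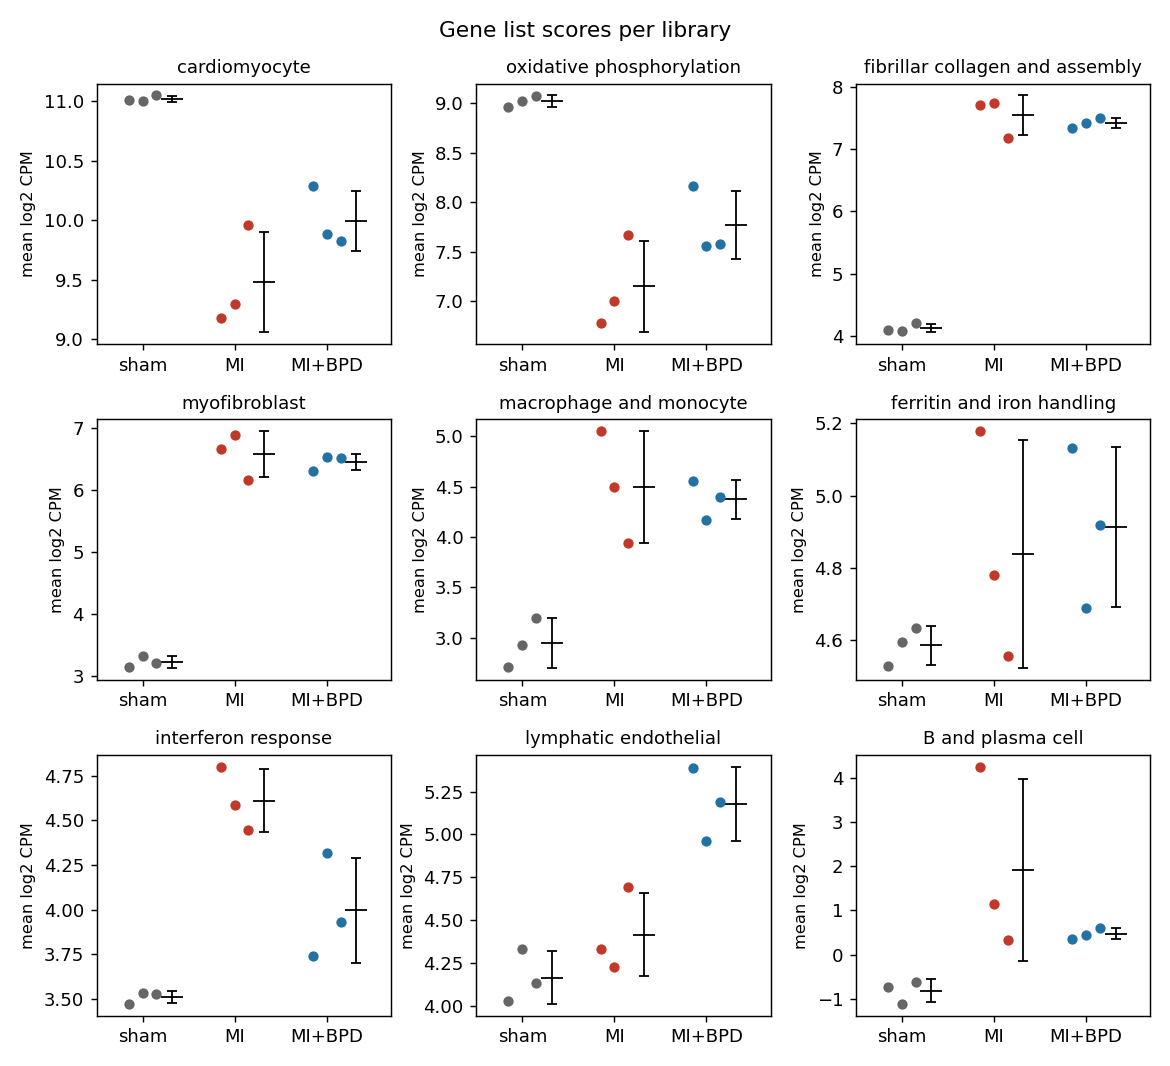
Scores of 9 gene lists per library (mean log2 CPM of the list's members), with points for the 3 libraries of each group and bars for the mean and SD. Interferon scores of the MI+BPD libraries (3.74, 4.32 and 3.93) lie below those of MI (4.80, 4.59 and 4.45), lymphatic scores lie above, and fibrillar collagen, myofibroblast and cardiomyocyte scores overlap between MI and MI+BPD.

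Of the 8 matrix and fibroblast lists with TGF-beta signalling, 5 did not pass in either direction. Fibrillar collagen and assembly had a mean of -0.12 (10 members above 0 and 24 below, adjusted p = 0.0607), matricellular and crosslinking -0.17 (12 and 22, 0.0607), myofibroblast -0.06 (10 and 15, 0.147), and matrix proteases and inhibitors -0.03 (8 and 16, 0.165). The resting fibroblast list had a mean of 0.03 (13 and 8, 0.180). In fry for changes of mixed direction, which gives no direction, its adjusted p was 7.4e-03. None of their members passed over all genes. Adjusted over the list alone 1 matricellular gene rose, Vcan (0.52 ± 0.11), and 2 resting fibroblast genes, Dpep1 and Dpt. Without MI replicate 3 the first 4 passed as lower, with adjusted p of 1.8e-04, 2.5e-04, 4.3e-04 and 3.7e-04. Without MI+BPD replicate 2 or 3 fibrillar collagen (0.0469 and 0.0253) and matricellular genes (0.0164 and 2.5e-04) did, as they did with the stricter filter (0.0315 and 0.0340), and matricellular genes also with a replicate block (-0.20, 0.0470). The matrix protease mean was above 0 without MI 1 (0.13), MI 2 (0.03) or MI+BPD 2 (0.03), the myofibroblast mean without MI 2 (0.11), and the resting fibroblast mean was below 0 without MI 2 (-0.008), MI 3 (-0.03) or MI+BPD 3 (-0.03), with upper-quartile factors (-0.02) and with library totals only (-0.18), none of them passing. The resting fibroblast list passed as higher without MI replicate 1 (2.2e-03) or MI+BPD replicate 1 (2.0e-04). With the cardiomyocyte score as a covariate all 5 passed as higher: fibrillar collagen (mean 0.18, 5.4e-06), matricellular (0.30, 4.5e-14), myofibroblast (0.24, 2.6e-04), matrix protease (0.21, 1.9e-04) and resting fibroblast genes (0.23, 1.7e-07). These p hold at the preset correlation only, and the spread between libraries was not computed for these 5 lists. For macrophage genes the same fit gave a camera adjusted p of 1.6e-09, but a difference of 0.2691 ± 0.415 (SE) between libraries. Matricellular (0.08, 2.3e-03) and resting fibroblast genes (0.25, 7.2e-12) also passed as higher without MI 1 and MI+BPD 1. In the panel Col3a1 was at 0.17 ± 0.22, Fn1 at -0.48 ± 0.30, Cthrc1 at -0.41 ± 0.23, Timp1 at 0.44 ± 0.23, Nppa at -0.53 ± 0.58, Nppb at -0.23 ± 0.31, Myh7 at -0.19 ± 0.49 and Tgfb1 at -0.29 ± 0.12.

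Of the matrix lists that passed as lower, matrifibrocyte genes were below 0 in 15 of 17 (mean -0.48, adjusted p = 3.1e-04, and adjusted p = 0.474 with an estimated correlation, 0.122 with library totals only), with Acan at -1.08 ± 0.32 and Prg4 at 1.16 ± 0.30. The matrifibrocyte score was 3.81 in MI+BPD replicate 1, against 5.18 and 4.93. Without that library the mean was -0.26 (0.0128), and without MI+BPD replicate 2 it was -0.73. The call ended without MI 1 and MI+BPD 1 (-0.15, 0.153) and with the cardiomyocyte covariate (0.03, 0.946). Basement membrane genes were below 0 in 14 of 18 (mean -0.24, adjusted p = 8.2e-05, and 0.474 with an estimated correlation), and Nid2 and Agrn (-0.50 ± 0.10) fell adjusted over the list alone. Without MI+BPD replicate 1 the basement membrane mean was -0.14 (0.0127), and the call ended without MI 1 and MI+BPD 1 (-0.10, 0.0733) and with the cardiomyocyte covariate (-0.07, 0.365). TGF-beta signalling was below 0 in 25 of 31 (mean -0.17, adjusted p = 1.2e-03, and 0.646 with an estimated correlation). Without MI+BPD replicate 1 its mean was -0.07 (0.255), without MI replicate 2 -0.11, without MI+BPD replicate 3 -0.26, without MI 1 and MI+BPD 1 -0.04 (0.875), and with the cardiomyocyte covariate it passed as higher (0.08, 0.0297). The means were -0.68 for matrifibrocyte, -0.43 for basement membrane (9.3e-04) and -0.37 for TGF-beta genes (9.1e-03) with library totals only.

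No iron gene passed between MI+BPD and MI in edgeR. Fth1 stood at 614 ± 29.5 CPM in MI and 766 ± 135 in MI+BPD (log2 change 0.32 ± 0.15, adjusted p = 0.380, SD, n = 3), Ftl1 at -0.16 ± 0.16, Tfrc at 0.29 ± 0.35, Slc40a1 at 0.21 ± 0.19 and Hmox1 at -0.01 ± 0.33. The ferritin and iron handling list had 18 members above 0 and 17 below, a mean of -0.01 and a median of 0.01 (camera direction higher, adjusted p = 0.306, and adjusted p = 0.649 with an estimated correlation). Of its members 0 passed, also adjusted over the list alone. Hmox2 at 0.29 ± 0.08, the iron regulator Hfe at 0.32 ± 0.11 and Hjv (hemojuvelin) at 0.79 ± 0.30 each had adjusted p = 0.369. Hjv stood at 53.8 ± 23.9 CPM in MI and 92.9 ± 31.0 in MI+BPD with overlapping libraries. Hmox2 and Hjv passed in limma-voom (0.03905 for both) and without MI replicate 3 (0.0383 and 0.0335), and with the cardiomyocyte covariate Hjv was at 0.06. Without MI replicate 1 the list passed as higher (mean 0.12, adjusted p = 9.1e-03), as it did with the cardiomyocyte covariate (0.16, 0.0240). Ferroptosis and antioxidant genes were above 0 in 23 of 31 (mean 0.12, adjusted p = 0.0106, and adjusted p = 0.474 with an estimated correlation), and 1 rose adjusted over the list alone, Nqo1. That call ended without MI replicate 3 (0.0557) or MI+BPD replicate 1 (0.0740, mean -0.05), without MI 1 and MI+BPD 1 (0.125), and with the cardiomyocyte covariate (0.345). Its mean had the opposite sign, -0.09, with library totals only (camera direction higher, 0.0446).

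Other lists that passed as lower did so under the preset correlation with 0 members called, also adjusted over the list alone. B and plasma cell genes had a mean of -2.48 (adjusted p = 2.0e-05), and -0.29 without MI replicate 1 (0.0720). Immediate early genes were at -0.30 (4.8e-03, 0.0829 without MI+BPD replicate 2), and DNA damage and senescence at -0.21 (0.0139, 0.150 without MI replicate 2). The unfolded protein response was at -0.15 (0.0207, 0.534 without MI replicate 2 and 0.0668 without MI+BPD replicate 2), and dendritic cell genes at -0.29 (0.0325, 0.0703, 0.0763 and 0.0668 without MI 1, MI 2 and MI+BPD 2). Epicardial and mesothelial genes were at -0.82 (5.3e-03). Without MI replicate 1 their mean was 0.40 (0.901), and without MI+BPD replicates 2 and 3 the adjusted p was 0.188 and 0.0586. With the cardiomyocyte covariate none of the 6 passed (adjusted p = 0.971, 0.839, 0.696, 0.345, 0.726 and 0.839, in the order given), and the dendritic cell (0.05) and epicardial means (0.15) lay above 0. With library totals only, DNA damage (-0.42, 0.122), dendritic cell (-0.51, 0.221) and epicardial genes (-1.13, 0.338) did not pass, and B and plasma cell (-2.75), immediate early (-0.51) and unfolded protein response genes (-0.36) did. Without MI 1 and MI+BPD 1 the B and plasma cell (0.207), immediate early (0.0989), DNA damage (0.0519) and dendritic cell calls (0.125) ended, the last also with upper-quartile factors (0.0602). With an estimated correlation the adjusted p of these 6 lists, in the order given, was 0.494, 0.635, 0.474, 0.573, 0.474 and 0.649.

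Lists that did not pass, with mean and adjusted p, were macrophage and monocyte (-0.16, 0.166, passing as lower without MI replicate 3 at 3.0e-04 or MI+BPD replicate 3 at 0.0356, with a mean of 0.20 without MI replicate 1 at 0.0893, and passing as higher with the cardiomyocyte covariate at 1.6e-09, mean 0.27), T and NK cell (-0.25, 0.147, passing as lower without MI replicate 3 at 0.0172, and as higher with the covariate at 0.0297, mean 0.29), fetal and stress genes (-0.24, 0.0683, passing as lower without MI 1 at 3.5e-03, MI+BPD 2 at 3.0e-03 or MI+BPD 3 at 0.0301, and with a replicate block at 0.0203), inflammatory cytokines (-0.09, 0.335, with a mean of 0.02 without MI 1 and 0.03 without MI 2) and hypoxia targets (0.04, 0.335). Also in this class were mast cell (-0.80, 0.147, passing as lower without MI 2 at 0.0134 or MI+BPD 1 at 6.98e-03, with a mean of 0.37 without MI 1 at 0.587), neutrophil (-0.84, 0.180, passing as lower without MI 2 at 0.0446 or MI+BPD 1 at 0.0226, with a mean of 0.72 without MI 1 at 0.135), pericyte and smooth muscle (0.11, 0.402, with a mean of -0.10 with library totals only), erythroid (0.11, 0.576, passing as higher with the covariate at 6.2e-04, with a mean of -0.006 without MI 3 and -0.01 without MI+BPD 2) and skeletal muscle (0.26, 0.520, with a mean of -0.03 without MI+BPD 3). Adipocyte genes had a mean of -0.79, a median of 0.17 and a camera direction of higher (0.369), with Pck1 lower adjusted over the list alone. Atrial genes (mean 0.07, median -0.03, 0.676) and Schwann cell genes (0.25 and -0.18, 0.559) also had means and medians of opposite sign.

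**Figure D2:**
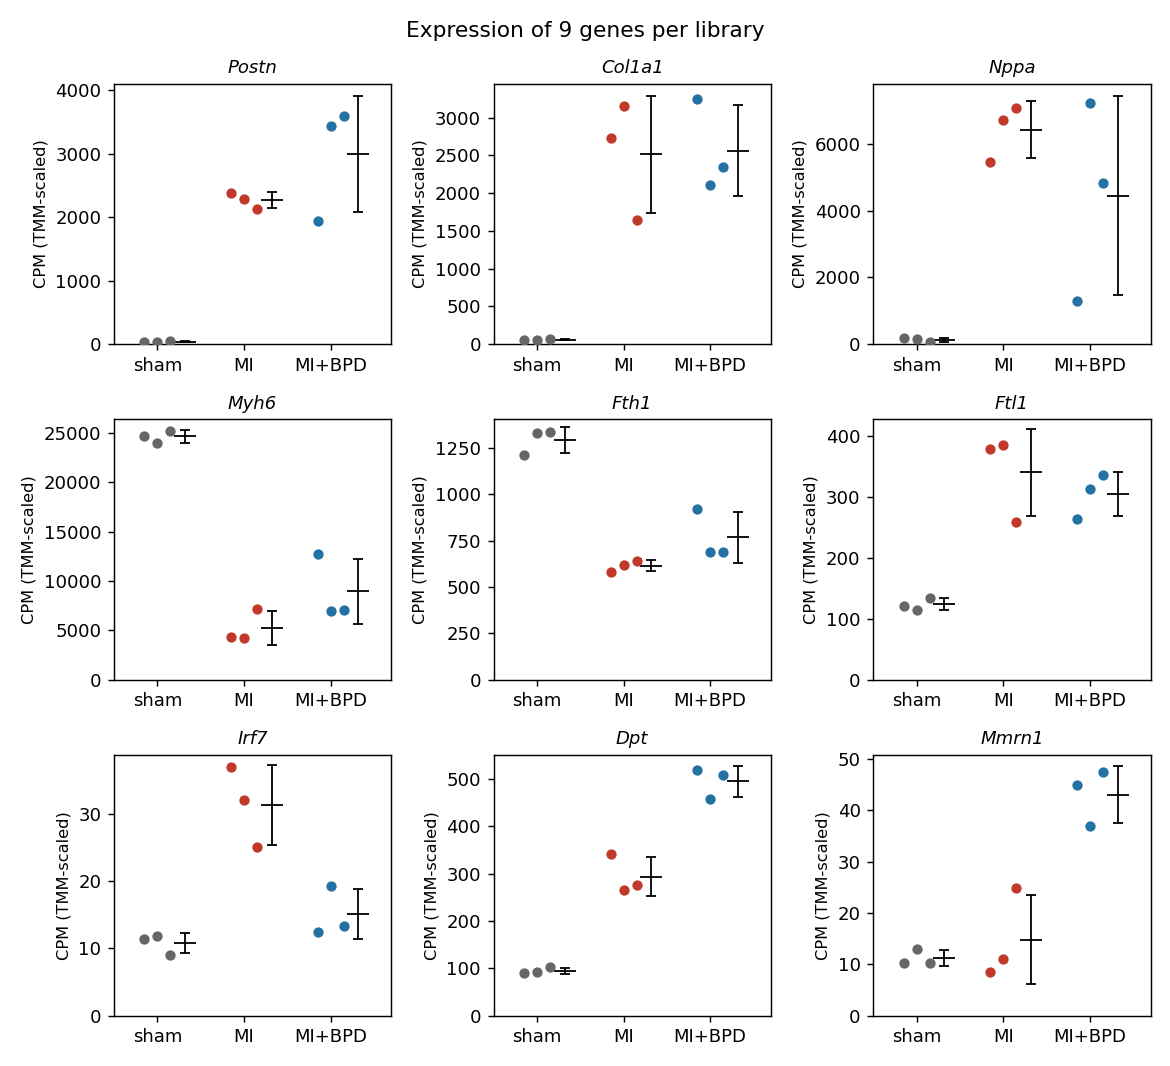
CPM of 9 genes per library (TMM-scaled, axes from 0), with points for the 3 libraries of each group and bars for the mean and SD. Postn, Col1a1, Fth1 and Ftl1 differ between sham and MI, and none of the 9 genes passed in edgeR between MI+BPD and MI.

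MI-responsive genes moved back under BPD are those of the 10429 called in MI against sham that are called with the opposite sign in MI+BPD against MI. In edgeR there were 0, where 1869 had an unadjusted p under 0.05 and the opposite sign and 27 the same sign. DESeq2 gave 46, limma-voom 949, and edgeR without MI replicate 3 gave 1331. In 88.8% of the 10429 genes the fold change of MI+BPD against MI had the opposite sign. Simulations in which no group differed gave 70.7% over as many genes of smallest p. They hold no infarct effect, so 70.7% is not the share expected after a real one. Both comparisons share the MI libraries, which alone makes opposite signs more frequent. Across genes the covariance of the log2 changes was -0.383, -0.040 in the simulations, and -0.048 from the spread of the MI libraries alone. With 3 MI libraries these controls cannot be split, so part of the excess of opposite signs may come from them.

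The comparison of MI+BPD with sham asks what of the infarct response is present under treatment. Postn rose by 6.30 ± 0.30, from 38.0 ± 4.40 to 2992 ± 919 CPM (SD, n = 3), Col1a1 by 5.46 ± 0.33, Col3a1 by 5.35 ± 0.26, Fn1 by 5.32 ± 0.37, Cthrc1 by 8.68 ± 0.42 and Timp1 by 6.21 ± 0.36. Myh6 fell by 1.46 ± 0.33 on the log2 scale, and Myh7, Nppa and Nppb rose by 4.40 ± 0.56, 5.14 ± 0.69 and 1.40 ± 0.32. In edgeR 9018 genes were called, 4816 higher and 4202 lower, of which 3801 changed at least 2-fold, 2625 higher and 1176 lower. Of the 10429 genes called in MI against sham 8744 (83.8%) were also called here, all with the same sign, 4662 higher and 4082 lower. Independent lists would share 1780 and 1342. The sham libraries serve in both comparisons. Simulations in which no group differed from sham gave 0.1 shared calls on average. With no effects to call this was fixed in advance, so it does not show what the shared sham libraries add.

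Among the 5158 genes changed at least 2-fold in MI, the fold change in MI+BPD was the smaller in 90.5%, with a median ratio of 0.793. Genes picked for a large change in MI tend to have a smaller one in any other group, and the difference itself is the comparison of MI+BPD with MI, in which 0 genes passed.

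**Figure D3:**
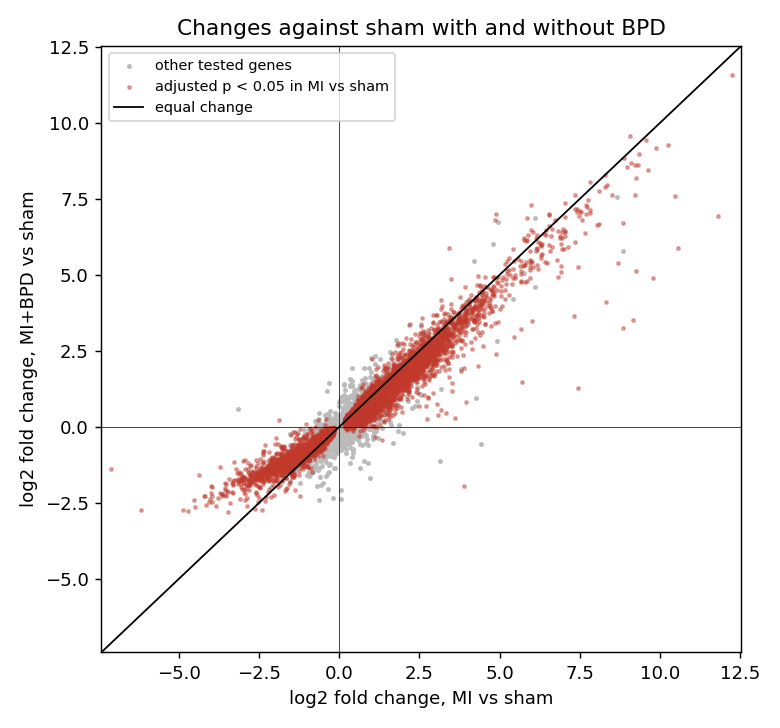
Log2 fold change of each tested gene in MI against sham (horizontal) and in MI+BPD against sham (vertical). Red points have an adjusted p under 0.05 in MI against sham and the line marks equal change. Among the 5158 genes changed at least 2-fold in MI the median ratio of the changes is 0.793, which places most of them on the side of the line nearer to 0 change in MI+BPD.

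Among the largest increases were again matrix and stress genes. Sprr1a was at least 256-fold and Cldn11, a tight junction protein, at least 63.7-fold higher, each with 0 sham counts. Cemip had a ratio of 772 (138 to 30500) and Cilp2 of 638 (114 to 25210), with 1 sham count each. Without sham replicate 3 these 4 were at least 161-fold, 40.2-fold, 162-fold and 134-fold higher. Col11a1 rose by 9.17 ± 0.67, C1qtnf3 by 8.85 ± 0.56, Col8a2 by 8.62 ± 0.71 and Comp by 8.60 ± 0.77. The largest decreases were Kcnv2 (-2.77 ± 0.58), Clcn1 (-2.60 ± 0.60), Acsm5 (-2.48 ± 0.57), Scn4b (-2.48 ± 0.67), Scd4 (-2.44 ± 0.42), Cngb3 (-2.42 ± 0.57), Ces1d (-2.36 ± 0.44), Timp4 (-2.35 ± 0.58), Ucp3 (-2.29 ± 0.36) and the mitochondrial transfer RNA mt-Tp (-2.27 ± 0.48). With no filter on low counts Scn4b (adjusted p = 0.0756) and Timp4 (0.0549) did not pass.

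Of 41 lists 24 passed, 15 higher and 9 lower, and 0 with an estimated correlation (smallest adjusted p = 0.123). Fry passed 32. All 34 matricellular genes rose (34 adjusted over the list alone, adjusted p = 4.5e-46, and adjusted p = 0.186 with an estimated correlation), as did 30 of 34 fibrillar collagen genes (30, 4.5e-46, and 0.123 with an estimated correlation) and 22 of 25 myofibroblast genes with 2 lower (22 and 2, 3.0e-15, and 0.197 with an estimated correlation). Macrophage and monocyte genes rose in 24 of 31 and fell in 1 (25 and 1 adjusted over the list alone, 9.9e-09, and adjusted p = 0.387 with an estimated correlation), and cell cycle genes rose in 34 of 38 and fell in 1 (34 and 1, 1.6e-09, and 0.295 with an estimated correlation). All 42 oxidative phosphorylation genes fell (42, 1.8e-13), as did 30 of 31 fatty acid oxidation genes (30, 1.1e-10) and 30 of 32 cardiomyocyte genes (30, 6.9e-09). With an estimated correlation these 3 had adjusted p = 0.438, 0.387 and 0.4585. Interferon response genes rose in 15 of 32, fell in 1 and did not pass in 16 (14 and 1 adjusted over the list alone, adjusted p = 0.0683). The list passed without sham 2 (0.0460), MI 1 (0.0470), MI+BPD 1 (0.0327) or MI+BPD 3 (0.0485), without MI 1 and MI+BPD 1 (0.0209), and with no filter on low counts (8.3e-04). Lymphatic endothelial genes rose in 4 of 6 and fell in 1 (4 and 1, adjusted p = 0.0550), with Mmrn1 at 1.94 ± 0.35 and Flt4 at 1.01 ± 0.14. That list passed without sham 2, MI 1, MI 3, MI+BPD 2 or MI+BPD 3, at adjusted p from 0.0129 to 0.0485, with library totals only (0.0451), median-ratio (0.0498) or upper-quartile factors (0.04999), with no filter on low counts (7.4e-03), and with the 2 groups alone (8.9e-03).

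Fth1 fell by 0.75 ± 0.15 on the log2 scale and Ftl1 rose by 1.30 ± 0.17. With library totals only Fth1 was at -0.24 and no longer passed (adjusted p = 0.104). Tfrc fell by 1.30 ± 0.35, Hmox1 rose by 1.59 ± 0.37 and Tgfb1 by 0.78 ± 0.13, while Slc40a1 (-0.13 ± 0.20) and Acta2 (0.41 ± 0.30) did not pass. With no filter on low counts Tfrc did not pass either (adjusted p = 0.0584), and with library totals only Acta2 did (0.95, 0.0263). Of the ferritin and iron handling list 11 rose, 7 fell and 17 did not pass (10 and 7 adjusted over the list alone, adjusted p = 0.945), with a mean of 0.39, a median of -0.05 and a camera direction of lower. The groups' libraries did not overlap in 68.5% of genes, where chance gives 10%. With library totals only the median of all genes moved from 0.04 to 0.57 and 86.8% of the called genes were higher, against 53.4%.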

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

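Library totals as the only scaling, leaving out MI 1 and MI+BPD 1 together, the cardiomyocyte score as a covariate and the further choices for the gene lists were chosen after the results were seen. Genes called in MI against sham and in MI+BPD against sham stayed within 1.5 times 10429 and 9018 under the other scalings, filters and tools, and fell to 5158 and 3801 with a log2 fold change of at least 1, a stricter threshold. In MI+BPD against MI edgeR gave 0 genes, DESeq2 51 and limma-voom with quality weights 992, with 0 to 1353 when 1 library was left out, the highest without MI replicate 3. MI-responsive genes moved back under BPD numbered 46 with DESeq2, 949 with limma-voom, and 0 to 1331 when 1 library was left out, again highest without MI replicate 3. Of the gene lists 0, 0 and 0 passed with an estimated correlation in the 3 comparisons, and 12 in MI+BPD against MI without MI 1 and MI+BPD 1. In that setting the matricellular list mean was 0.0772. With the cardiomyocyte covariate the direction in MI+BPD against MI turned over for these lists called with or without it: TGF-beta signalling 0.08223, T and NK cell 0.2935, antigen presentation 0.06636, cardiomyocyte -0.0006982, fibrillar collagen 0.1829, glycolysis -0.02937, iron-sulfur and heme synthesis -0.0128, macrophage 0.2656, matricellular 0.3019, matrifibrocyte 0.0262, matrix proteases 0.2093 and myofibroblast 0.244. The means of dendritic cell (0.053), epicardial (0.147), neutrophil (0.366), adipocyte (0.0725), cytokine (0.0712), ferritin (0.158), endothelial (-0.0434) and atrial lists (-0.0807) changed sign as well, and of these ferritin passed. The cardiomyocyte value follows from the covariate itself. In MI against sham Hba-a1 was at 0.5181 and Hmox2 at 0.03724 with library totals only, and Cpa3 at -1.58 without MI 1 and MI+BPD 1. Apart from the threshold and the cardiomyocyte value, the cause was not tested. The interferon, lymphatic, cell cycle and fatty acid oxidation lists kept direction and threshold in MI+BPD against MI in 19 of 19 settings with the preset correlation. Their largest adjusted p was 1.1e-14, 2.5e-04, 1.0e-04 and 0.0200. The cardiomyocyte list did so in 18. All these settings keep the real groups. Other splits of the MI and MI+BPD libraries gave up to 28 lists at the preset correlation, against 21 with the real one. Some values called neither in the main fit nor in the alternative also turned over. For MI against sham, MI+BPD against MI and MI+BPD against sham these were 17, 28 and 26 list values by camera direction. By the sign of the fold change they were 11, 64 and 8 named gene values. The 13 list values and 3 named gene values that turned over with a call are those given above. Same-numbered MI+BPD and MI libraries correlated at 0.143, 0.194 and -0.158, and a replicate block gave 10054, 0 and 8457 genes and 27, 23 and 24 lists. At this depth and group size simulated 1.5-fold changes were called in 31.3%, 34.3% and 20.9% of cases and 4-fold changes in 97.0%, 92.4% and 92.4%. These shares may be too high as well, because the simulated genes were independent and had the same dispersion in all groups.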

Other observations

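The splits of the libraries were planned, and the tests of the 3 patterns below were chosen after the results were seen. MI replicate 1 had higher scores than the other MI libraries for B and plasma cell genes (4.24, against 1.14 and 0.34), mast cell genes (2.31, against 0.58 and 0.30) and neutrophil genes (2.35, against -0.01 and -0.30). Its epicardial and mesothelial score was 4.21, against 2.55 and 1.03. MI+BPD replicate 1 had a matrifibrocyte score of 3.81, against 5.18 and 4.93, and Nppa at 1282 CPM, against 7228 and 4830. Cyp1a1, picked after its values were seen because DESeq2 called it, was at 0, 0 and 0.046 CPM in MI and at 1.20, 0.051 and 2.03 CPM in MI+BPD.

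With the real one there are 10 splits of the same 6 libraries per comparison, too few for a share under 0.05. In MI against sham 1 of the 10, the real one, gave 10429 genes and the highest of the 9 others 0, and 4 of the 10 gave at least the real number of lists (26, highest other 29). In MI+BPD against MI the real split gave 0 genes in edgeR (highest other 1, with 2043 at an unadjusted p under 0.05 in the real split). DESeq2 gave 51 and limma-voom 992. No split can give fewer than 0, so the edgeR gene counts cannot tell the real split from chance. At least the real number of lists came from 6 of the 10 (21, highest other 28). In MI+BPD against sham 1 of the 10, the real one, gave 9018 genes and the highest of the 9 others 0, and 5 gave at least the real number of lists (24, highest other 25). In both comparisons with sham, every split but the real one mixes the groups. A large difference between the groups then widens the spread within the mixed ones and holds down gene calls. The 0 genes of those splits therefore show little about chance. For genes moved back the real split gave 0 (highest other 1), and again no split can give fewer, so this count decides nothing.

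Heart muscle and energy lists were higher in MI+BPD than in MI. A single library as the whole source is argued against by the left-out fits, where the mean nearest 0 was 0.3128 (without MI+BPD replicate 1), although it was 0.176 (adjusted p = 3.2e-05) without MI 1 and MI+BPD 1, and the mitochondrially encoded mean went from 1.07 to 0.53 without MI+BPD replicate 1. Scaling of the libraries moves the cardiomyocyte mean, from 0.4934 with TMM to 0.2943 with library totals only. The cardiomyocyte score above each library's median gene, which no scaling factor moves, differed by 0.4975 ± 0.276 (SE, n = 3). By construction this measure is the same under any scaling, so it does not show whether the cardiomyocyte difference depends on scaling. The libraries overlap in this measure, so it leaves undecided whether the groups differ. A larger share of heart muscle in the sampled tissue may explain both lists: the energy score minus the cardiomyocyte score differed by 0.12 ± 0.073 (SE, n = 3, exact permutation p = 0.3), with overlapping libraries, which leaves it open. Other cell types would then be lower, which the scaling decides: with TMM the scores of pericytes (0.1065 ± 0.0265, no overlap), endothelium (0.118 ± 0.0906) and resting fibroblasts (0.0342 ± 0.132) were higher and that of macrophages lower (-0.12 ± 0.34), while with library totals only all 4 list means were lower (-0.09947, -0.09374, -0.1779 and -0.3926), so muscle share stays open, as does an effect of BPD on surviving muscle, which was not tested.

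Interferon response genes were lower in MI+BPD than in MI. A single library as the whole source is argued against by the mean nearest 0 in the left-out fits, -0.499 (without MI replicate 1), although it was -0.3944 (adjusted p = 6.9e-19) without MI 1 and MI+BPD 1, against -0.6111 with all libraries. A larger share of heart muscle may contribute: with the cardiomyocyte score as a covariate the list mean was -0.3517 (adjusted p = 1.1e-14, the largest over its 19 settings), but between libraries the score differed by -0.3658 ± 0.227 (SE, 3 residual degrees of freedom, 95% interval -1.089 to 0.357), so this stays open. Fewer macrophages and monocytes could be a source: the interferon score minus the macrophage score differed by -0.4959 ± 0.358 (SE, n = 3, exact permutation p = 0.3), with overlapping libraries. With the covariate the macrophage list mean was higher in MI+BPD, 0.2656 ± 0.0471 (SE over members, adjusted p = 1.6e-09), which goes against fewer macrophages, but between libraries it was 0.2691 ± 0.415, so this stays open as well, as does a lower interferon response under BPD, which was not tested apart from these.

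Lymphatic endothelial genes were higher in MI+BPD than in MI. More endothelium of every kind is argued against by the lymphatic score minus the endothelial score, 0.6421 ± 0.12 (SE, n = 3). Heart muscle also expresses Prox1, and without Prox1 the score differed by 0.7703 ± 0.17. Both measures were without overlap between the groups (exact permutation p = 0.1, the smallest possible). Prox1 alone thus does not carry the difference. Its own change lay near the list mean, so leaving it out could alter little and does not test a larger share of heart muscle. With the cardiomyocyte score as a covariate the score without Prox1 differed by 0.5398 ± 0.179 between libraries (SE, 3 residual degrees of freedom). Its 95% interval, -0.0288 to 1.108, includes 0, so a larger share of heart muscle stays open. More outer heart wall in the sampled piece might contribute: the lymphatic score minus the epicardial score differed by 1.385 ± 1.18 with overlapping libraries (exact permutation p = 0.3), which decides nothing. Growth of lymphatic vessels under BPD stays open and was not tested.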
